A study of Homo sapiens with 6 samples.

How the data were processed

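RNA of cells labelled Huh7, treated for 24 h with sorafenib or DMSO, was measured on an Illumina expression beadchip, with 3 arrays per group. Per the labels' protocols, RNA was extracted with a spin kit, treated with DNase, checked for purity and integrity, and turned into biotin-labelled cRNA with a TargetAmp kit. Groups and replicate numbers came from the sample titles. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

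The authors deposited probe signals of all 6 samples as intensity on a linear scale, not normalized between arrays, per the file headers. Beside each signal the authors deposited a detection p-value, per the file headers, which moves in steps of about 1/770 in the files. The deposited value table holds 1 column per sample. From its values it was taken to be on a log2 scale, since all 6 columns ran from 6.08 to 15.85 with a median of 7.10 and shared 1 distribution, as quantile normalization gives. Whether the deposited log2 values had a background subtracted, and how they were otherwise made, is unknown. The scanner software, its version and the normalization tool are not given in the sources used here.

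The value table was set against the signals column by column before it was used. It did not hold the values of the same arrays. For 3 of 6 samples, the signal column correlated best with the value-table column of the same sample. The Spearman correlation of a sample's own 2 columns across probes was at most 0.863. The signals were analysed as the main data, as fixed before the data were examined, and the value table served both as the alternative source fixed at that time and as a separate set of arrays with its own filter, which was added after the data were seen. Tests of sorafenib's effect were run only within a set, and the sets were normalized separately. Levels were compared across the sets in the checks of whether the sets hold the same arrays, for single genes, and for 1 list of beta-catenin targets, set against random lists of the same mean level. These comparisons describe the values and are not tests between replicates.

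Signals were background-corrected and quantile-normalized with limma's neqc, which took the background's mean and SD from the detection p-values, with an offset of 16, and were put on a log2 scale. Probes with a detection p under 0.01 on at least 3 of the 6 arrays were kept, whatever their group, which left 17115 of 47323. The detection threshold corresponded to a normalized log2 level of 5.98 to 6.18 over the arrays. In the value table, probes above a log2 level of 7.40, the mean level of that threshold in the signals without background correction, on at least 3 columns were kept (17122). Arrays of 1 group correlated at r = 0.989 to 0.995 across kept probes of the signals and arrays of different groups at 0.973 to 0.984; in the value table the ranges were 0.992 to 0.997 and 0.982 to 0.992. No 2 arrays held identical values.

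Gene symbols came from a table of the platform's annotation. Of its probes, 30113 had 1 symbol, 8 had several and 17202 had none, and 30074 were matched by Entrez identifier to current symbols, of which 0 changed. Probes with several symbols or none were tested but not named. The kept probe with the highest mean level stood for its gene, and no named gene had kept probes that passed in opposite directions. No genome coordinates were used.

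Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the intensity trend, two-sided, group only) and adjusted by Benjamini-Hochberg over all kept probes, with a threshold of 0.05. Changes beyond 1.5-fold were tested with limma's treat. A gene detected on no array of a group has only a bound there. Its fold is given as at least the ratio of the brighter group's mean to the mean, over the dimmer group's arrays, of the higher of the array's detection level and the probe's own level. In the value table the filter's level took the place of the detection level. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, adjusted over 21 lists. The lists, of 607 entries with 570 on a named probe, covered the PDI family, ER chaperones and degradation, ATF4 and CHOP targets, aminoacyl-tRNA synthetases, RAF-MEK-ERK output, DNA replication and S phase, mitosis, cholesterol synthesis and LDL uptake, fatty acid synthesis, hypoxia and glycolysis, NRF2 targets, metallothioneins, heat shock, secreted hepatocyte proteins, bile acid and xenobiotic metabolism, oxidative phosphorylation, cytosolic ribosomal proteins, apoptosis regulators, autophagy and lysosome, inflammation and interferon, and stromal, endothelial and immune markers.

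The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 15 largest rises and 15 largest falls among genes past the threshold whose arrays did not overlap between groups, a separation chance gives in 10% of genes. It also took, in each list, the 2 largest rises and 2 largest falls past the threshold (or the 2 brightest members), and P4HB, HSPA5, XBP1, DDIT3, ATF4, TRIB3, DUSP6, SPRY4, CCND1, MCL1, MKI67, ALB and AFP; 1 further gene of the rule is not reported here. The same rule was applied to each set.

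The titles number the replicates, and the labels do not say whether samples of the same number belonged together. Deviations of same-numbered DMSO and sorafenib arrays from their group means correlated, across probes, at 0.337, 0.321 and 0.385 in the signals and 0.432, 0.317 and 0.666 in the value table. For different numbers the correlations ran from -0.354 to 0.0331 in the signals and from -0.518 to 0.294 in the value table. The fit without the number as a block stayed the main fit, as fixed before, and blocked values are given where they change a call or move a count by over 1.5 times.

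The alternatives were no background correction, normexp with an offset of 50, cyclic loess, median scaling, no filter, detection on all 6 arrays, no intensity trend, a robust prior, array weights, the value table in place of the signals, the replicate block, the mean of a gene's probes, an estimated correlation and leaving out each array. A slide block was not run, since the files give no slide.

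The fits were tested on simulated data for each set, in 12 draws of all kept probes with 200 of them changed, 50 at each size. With SDs drawn from limma's fitted prior, the signals' fit called 6.50%, 54.2%, 83.7% and 98.8% of probes changed by 0.3, 0.6, 1 and 2 log2 units, with 4.67% of calls false. With SDs set to the posterior values of the real probes, which are shrunken, 11.5%, 65.3%, 89.7% and 100% were called and 7.89% of calls were false. For the value table the shares were 8.67%, 76.5%, 97.8% and 99.8% with 4.64% false, and 18.0%, 93.8%, 99.5% and 100% with 7.89% false. All true calls had the right sign, a list shifted by 0.3 was called by camera and fry, and of 20 unshifted lists camera called 0 and fry at most 1. The lists were tested on 1 of the 12 draws only, and simulated probes were drawn independently of each other. Genes of the real lists were correlated, with an estimate of 0.634 for secreted hepatocyte proteins in the signals. The simulation therefore does not give the rate of false list calls in the real data. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.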

Results

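Gene expression was measured in hepatocellular carcinoma cells labelled Huh7, a human liver cancer line, after 24 h with sorafenib or with the solvent DMSO alone. Sorafenib is an oral kinase inhibitor used against this cancer; its targets include the RAF kinases and the receptors for VEGF and PDGF. The labels give its concentration as 3 mM, and whether another unit was meant was not settled. The design held 3 DMSO and 3 sorafenib samples, each on its own Illumina expression beadchip array. The series title sets the experiment beside inhibition of protein disulfide isomerase (PDI), an enzyme of the endoplasmic reticulum (ER) that forms disulfide bonds in new proteins, and the comparison asks which genes sorafenib alone raised or lowered.

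The 6 samples carried 2 deposited sets of values, probe signals that were not normalized and a table of normalized values, and the sets were not measurements of the same arrays. Across probes, which are not independent replicates, the Spearman correlation of a sample's own 2 columns was 0.848 to 0.863, and that of different samples across the sets 0.846 to 0.863. Different arrays within 1 set correlated at 0.923 to 0.942. The sets are called the signal arrays and the value-table arrays. They were normalized separately and each was tested on its own, and no difference between them in the response to sorafenib was tested. Which of them came from Huh7 cells was not settled. Levels set side by side across them describe separately normalized values. In all, 15217 probes were kept in both sets, 1898 on the signal arrays alone and 1905 on the value-table arrays alone. Over the probes kept in either set, the median absolute difference in level was 0.39 on the log2 scale, and 401 probes differed by over 3 log2 units. The glucose transporter SLC2A3 lay at 14.88 on the signal arrays, taken without background correction, and 6.64 on the value-table arrays, and the tetraspanin CD81 at 6.93 and 14.28; these genes were chosen after their values were seen.

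**Figure D1:**
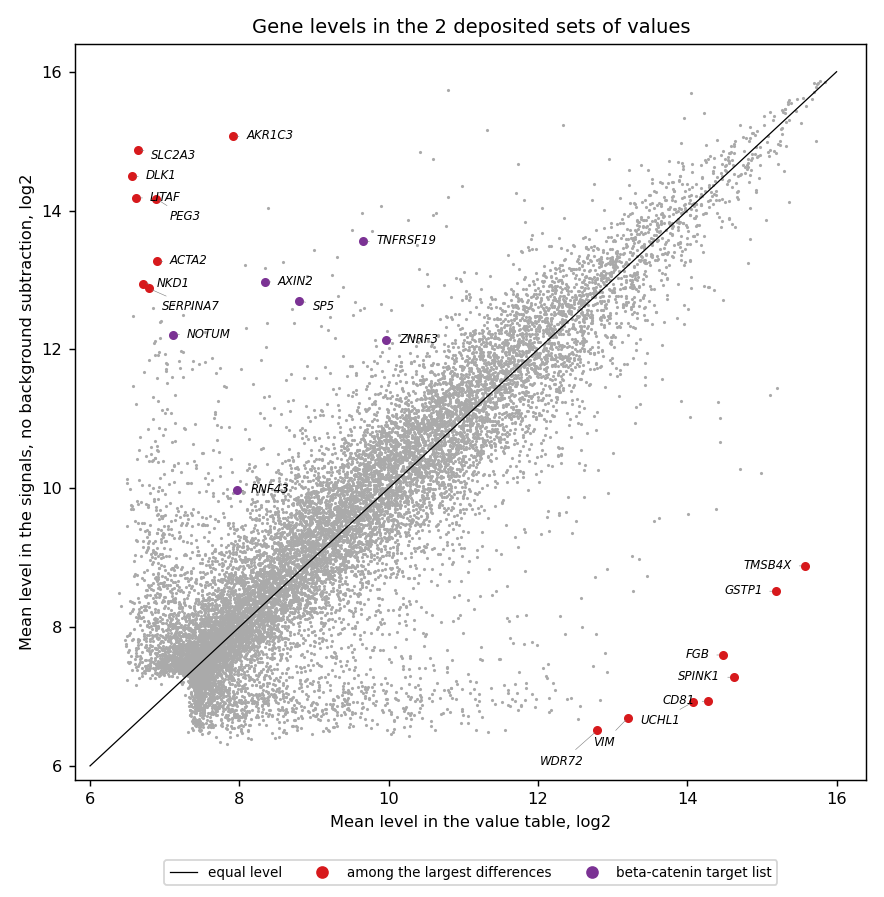
Mean log2 level of each named probe over 6 columns of the value table (horizontal axis) and over the 6 signal arrays without background correction (vertical axis), with the line of equal level. SLC2A3 at 14.88 against 6.64 and CD81 at 6.93 against 14.28 lay on opposite sides of the line, and purple points are genes of a beta-catenin target list.

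The median signal of the 6 signal arrays was 120.2 to 144.5, and 16476 to 17476 of 47323 probes were detected per array at the detection threshold. The number of arrays, 3 per group, limits the precision of every value.

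On the signal arrays, sorafenib lowered feedback regulators and targets of the RAF-MEK-ERK kinase cascade. SPRY4 (probe ILMN_2086105), a feedback inhibitor of receptor tyrosine kinase signalling, fell 7.85-fold, from a log2 level of 13.11 ± 0.28 to 10.13 ± 0.41 (SD, n = 3 per group; log2 change -2.97, SE 0.19, limma adjusted p = 1.14e-05). DUSP6 (probe ILMN_2396020), the phosphatase that inactivates ERK, fell 6.71-fold, from 11.53 ± 0.16 to 8.79 ± 0.43 (log2 change -2.75, SE 0.18, adjusted p = 1.22e-05). The ETS transcription factor ETV4 fell 5.05-fold and the immediate early gene IER3 4.83-fold. The stress-induced transcriptional regulator NUPR1 moved the other way and rose 4.13-fold, from 8.80 ± 0.09 to 10.84 ± 0.10 (adjusted p = 1.00e-06).

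Other genes fell as well, and whether they respond to the RAF-MEK-ERK cascade was not tested. DKK4 (probe ILMN_1712729), a secreted WNT antagonist, fell 11.4-fold, from 11.12 ± 0.09 to 7.61 ± 0.14 (SD, n = 3; log2 change -3.51, SE 0.10, limma adjusted p = 1.05e-07). The chemokine CCL20 fell 9.09-fold, from 12.11 ± 0.07 to 8.93 ± 0.05 (log2 change -3.18, SE 0.07, adjusted p = 2.55e-08). FST, which encodes the activin antagonist follistatin, fell 4.45-fold, and IGFBP1, an insulin-like growth factor binding protein, 5.56-fold. NR0B2, a nuclear receptor that represses bile acid synthesis, fell 5.72-fold. The homeobox genes HOXD1 and MIXL1 fell 7.31-fold and 4.87-fold. The sorafenib means of MIXL1 and IGFBP1, 6.30 and 6.42, lay near the arrays' detection levels of 5.98 to 6.18, so the sizes of these 2 falls are uncertain. HEY1, a transcription factor induced by Notch, was not detected on any sorafenib array and was at least 4.86-fold lower there, while PPP2R2C and TAGLN3 also fell (adjusted p = 5.18e-06 and 0.000199). Both were detected on 1 of 3 sorafenib arrays, with sorafenib means of 6.02 and 5.87 that lay under those arrays' mean detection level, so no size is given.

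Genes that rose included BMF (probe ILMN_1695354), a pro-apoptotic member of the BCL2 family. BMF was not detected on any DMSO array, reached 8.36 ± 0.17 with sorafenib (SD, n = 3) and was at least 4.93-fold higher (limma adjusted p = 4.90e-06). GNMT, the glycine methyltransferase of liver, was likewise undetected with DMSO and at least 3.95-fold higher with sorafenib. The lower bounds for TNNC2, a muscle troponin, and KNG1, the kininogen secreted by hepatocytes, were 2.46-fold and 2.05-fold. Among genes detected in both groups, PLA2G1B, a secreted phospholipase, rose 5.71-fold, the calpain CAPN3 5.15-fold, the thyroid hormone deiodinase DIO1 4.39-fold and the glutathione transferase GSTA5 4.04-fold. IFIT1, an interferon-induced gene, rose 3.92-fold and the apolipoprotein APOC3 3.75-fold. The adjusted p of these genes lay between 3.51e-06 for GSTA5 and 0.00132 for KNG1.

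Over all signals, 4582 of 17115 probes passed limma's adjusted threshold, 2417 higher and 2165 lower with sorafenib, against 6653 at an unadjusted p under 0.05. Counted once per gene, 1767 of 10523 genes rose and 1493 fell. A change beyond 1.5-fold was shown for 221 probes, 136 up and 85 down, or 409 with the replicate number as a block. With this block 3363 probes passed as higher and 3385 as lower, and 2363 genes rose and 2264 fell. The first count was 2627 with median scaling and 2946 without DMSO replicate 2; the count beyond 1.5-fold was 135 without background correction, 147 with normexp, 144 without DMSO replicate 2 and 142 without sorafenib replicate 2.

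**Figure D2:**
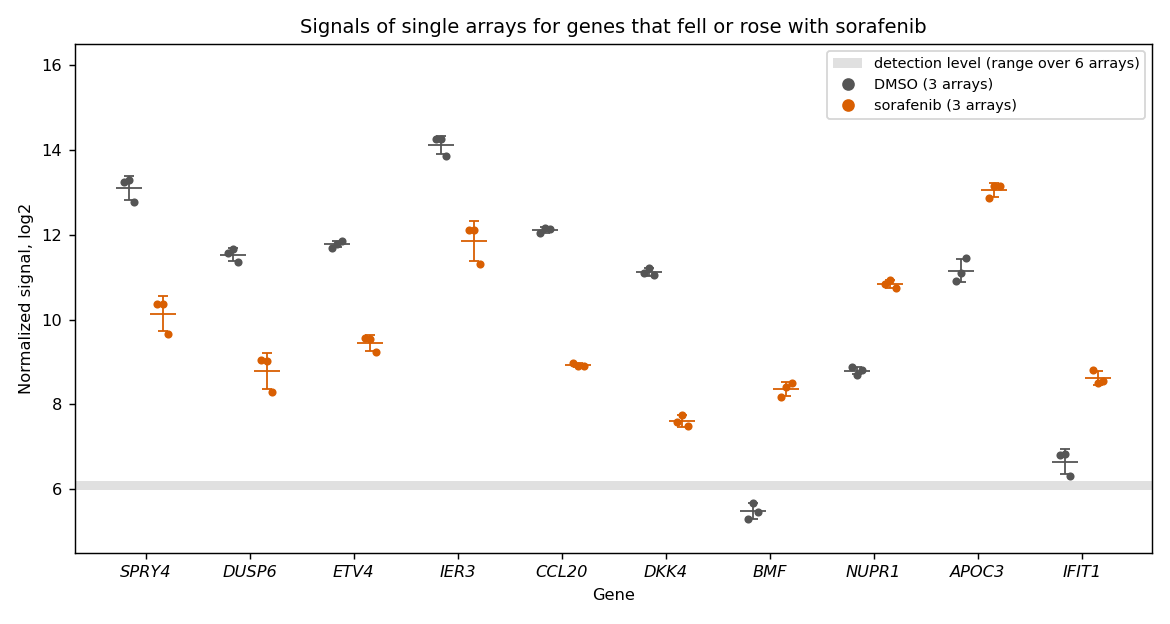
Normalized log2 signal (vertical axis) of 10 genes on the single signal arrays (points; DMSO grey, sorafenib orange; bars are mean and SD, n = 3), with the range of the arrays' detection levels as a grey band. SPRY4 lay at a mean of 13.11 with DMSO and 10.13 with sorafenib, and the DMSO points of BMF lay under the band.

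Of the 21 gene lists, 7 shifted on the signal arrays by limma's camera with its preset correlation. In the RAF-MEK-ERK list, 19 of 20 measured genes fell and none rose, 19 also when adjusted over the list alone (median log2 change -1.19, camera adjusted p = 5.42e-14). This call was lost at adjusted p = 0.550 with an estimated correlation. The remaining member was CCND1, which encodes cyclin D1, with a log2 change of -0.10 (adjusted p = 0.394). DUSP5, another ERK phosphatase, fell 5.45-fold (log2 change -2.45, SE 0.45, limma adjusted p = 0.00357). A change beyond 1.5-fold was not shown for DUSP5 (treat adjusted p = 0.0726).

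By camera the replication and mitosis lists fell, and the cholesterol and fatty acid lists rose. Of 32 replication and S phase genes, 17 fell and none rose, 20 when adjusted over the list alone (median -0.30, camera adjusted p = 3.45e-07, adjusted p = 0.674 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell 2.33-fold (SE of the log2 change 0.14, adjusted p = 0.000342). Of 35 mitosis genes, 23 fell and none rose, 27 when adjusted over the list alone (median -0.26, camera adjusted p = 3.45e-07, adjusted p = 0.674 with an estimated correlation), and the proliferation marker MKI67 fell 1.75-fold. Of 19 genes of cholesterol synthesis and LDL uptake, 14 rose and none fell, 15 when adjusted over the list alone (median 0.47, camera adjusted p = 4.97e-06, adjusted p = 0.674 with an estimated correlation). LSS, which encodes lanosterol synthase, rose 2.19-fold and the sterol reductase gene TM7SF2 2.18-fold. In the fatty acid list, 9 of 14 genes rose and 1 fell, with the same counts when adjusted over the list alone (median 0.36, camera adjusted p = 0.000328, adjusted p = 0.674 with an estimated correlation). The acetyl-CoA synthetase ACSS2 rose 2.28-fold, the phosphatidate phosphatase LPIN1 1.61-fold, and SREBF1, a transcription factor that drives the pathway, was the member that fell (log2 change -0.42), a call lost under median scaling at the same log2 change of -0.42 (adjusted p = 0.0780).

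By camera, the ER chaperone and degradation list fell and the PDI family was not called, although fry called the PDI family down (adjusted p = 0.0279). Of 30 chaperone and degradation genes, 14 fell and 1 rose, with the same counts when adjusted over the list alone (median -0.33, camera adjusted p = 1.05e-06, adjusted p = 0.207 with an estimated correlation). HSPA5, the main HSP70 chaperone of the ER, fell from 10.41 ± 0.10 to 9.63 ± 0.09 (SD, n = 3, adjusted p = 0.000242), and XBP1, a transcription factor of the unfolded protein response, from 13.96 ± 0.16 to 13.28 ± 0.05 (adjusted p = 0.000343). OS9, a lectin of ER-associated degradation, was the member that rose (log2 change 0.47). Of 15 PDI family genes, 2 rose and 5 fell, also when adjusted over the list alone (median -0.12, camera adjusted p = 0.197). P4HB, which encodes PDI itself, had a log2 change of -0.12 (SE 0.06, adjusted p = 0.157), ERP27 rose 1.54-fold and TXNDC5 fell 1.33-fold.

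The list of secreted hepatocyte proteins shifted up by camera. Of its 35 measured genes, 17 rose, 4 fell and 14 did not pass, 21 and 5 when adjusted over the list alone and 22 and 7 with the replicate block (median 0.40, camera adjusted p = 0.000237, adjusted p = 0.689 with an estimated correlation). APOC3 rose from 11.15 ± 0.27 to 13.06 ± 0.16 (SD, n = 3), whereas the apolipoproteins APOM and APOB fell 2.08-fold and 1.45-fold. ALB, the albumin gene, had a log2 change of 0.01 (SE 0.11, adjusted p = 0.969), and the fetal liver marker AFP fell 1.22-fold. In 17 other settings of the signal arrays, the highest camera adjusted p of the 7 shifted lists was 0.00344, for this list without sorafenib replicate 3. However, the other 9 divisions of the 6 arrays into 3 and 3 called up to 9 lists by the same test. Each of these divisions mixed the groups and kept part of the sorafenib difference. They therefore do not show how many lists would be called without a sorafenib effect.

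ATF4 is the transcription factor of the amino acid and ER stress response, and CHOP, encoded by DDIT3, acts downstream of it. Of their 35 measured targets, 15 rose and 5 fell, 16 and 7 when adjusted over the list alone and 17 and 8 with the replicate block, and the list was not called by camera (median 0.21, camera adjusted p = 0.0687, adjusted p = 0.689 with an estimated correlation). It was called at 0.0286 with array weights, 0.0363 with the mean of a gene's probes and 0.00768 without sorafenib replicate 3, within a range of 0.00768 to 0.175 over 17 settings of the signal arrays at the preset correlation. DDIT3 rose 1.48-fold and KLHL24, detected on 2 of 3 DMSO arrays, had a log2 change of 0.98. GDF15, a secreted stress cytokine, fell 3.08-fold. ATF4 itself had a log2 change of 0.26 (adjusted p = 0.0244) and the pseudokinase TRIB3 of 0.31 (adjusted p = 0.0159). Their calls held in 2 and 3 of the 6 fits that left out 1 array, lost for ATF4 without DMSO replicate 2 or 3 or sorafenib replicate 1 or 2 (log2 change 0.20 to 0.27) and for TRIB3 without DMSO replicate 2 or sorafenib replicate 2 or 3 (0.26 to 0.32), and both were lost under median scaling (log2 change 0.21 and 0.28) and without the intensity trend (adjusted p = 0.0833 and 0.0540). ATF4's call was also lost with the mean of its probes (log2 change 0.18, adjusted p = 0.111). Of 18 aminoacyl-tRNA synthetases, which charge transfer RNAs, 1 rose and 4 fell, also over the list alone, and 1 and 7 with the replicate block (median -0.13, camera adjusted p = 0.0816, but 0.0489 without sorafenib replicate 1 and 0.0455 without sorafenib replicate 2, the lowest of a range to 0.239 over 17 settings). With an estimated correlation the synthetases' adjusted p was 0.689. FARSA and VARS1 fell by 0.58 and 0.48 on the log2 scale.

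Other lists held genes that moved both ways and were not called by camera on the signal arrays. In the hypoxia and glycolysis list, 4 of 31 genes rose and 6 fell, also over the list alone (camera adjusted p = 0.249). Hexokinase HK2 fell 3.34-fold and the glucose transporter SLC2A1 2.12-fold. PFKFB4, an enzyme that regulates glycolysis, rose 1.81-fold and the glycolytic enzyme ALDOC 1.69-fold. Of 22 NRF2 targets, 6 rose and 6 fell, 7 and 7 when adjusted over the list alone (adjusted p = 0.740). The glutathione transferase GSTA1 rose 2.70-fold and the aldo-keto reductase AKR1B10 fell 2.02-fold. Of 11 bile acid and xenobiotic genes, 4 rose and 2 fell, 5 and 2 over the list alone (adjusted p = 0.279), among them the sulfotransferase SULT2A1, which rose 2.37-fold. Of 9 metallothionein list genes, 2 rose and 2 fell, also over the list alone, and 5 and 2 with the replicate block (adjusted p = 0.717). MT1F rose 1.57-fold and MT2A fell 1.70-fold. Of 19 heat shock genes, 1 rose and 3 fell, also over the list alone, and 2 and 6 with the replicate block (adjusted p = 0.279), with HSPB1 1.47-fold higher and the HSP90 co-chaperone FKBP4 1.67-fold lower.

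The inflammation and interferon list held genes that moved both ways. Of its 17 measured genes, 7 rose and 5 fell, also over the list alone (camera adjusted p = 0.740). Its median log2 change was 0.03 and its mean -0.09, and the direction was up by camera and down by fry (adjusted p = 0.0280). CXCL8, a neutrophil chemokine, fell 3.24-fold (SE of the log2 change 0.31, limma adjusted p = 0.00361). A change beyond 1.5-fold was not shown for CXCL8 (treat adjusted p = 0.143). IFIT3, undetected with DMSO, was at least 1.495-fold higher with sorafenib. Of 20 apoptosis regulators, 5 rose and 2 fell, also over the list alone, and 8 and 3 with the replicate block (adjusted p = 0.472). BOK, a pro-apoptotic member, rose 1.43-fold, and the anti-apoptotic members BCL2L1 and MCL1 fell 1.49-fold and 1.41-fold. Of 27 autophagy and lysosome genes, 5 rose and 4 fell, also over the list alone (adjusted p = 0.313). The lysosomal sialidase NEU1 rose 1.78-fold and the autophagy kinase ULK1 had a log2 rise of 0.68.

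Among 32 oxidative phosphorylation genes, 5 rose and none fell, 3 when adjusted over the list alone and 9 with the replicate block (camera adjusted p = 0.140). Of 37 cytosolic ribosomal protein genes, 1 rose and 1 fell, 0 and 1 over the list alone and 3 and 2 with the replicate block (adjusted p = 0.570). RPS7 was the ribosomal gene that fell, by 1.55-fold. Markers of stromal, endothelial and immune cells had 5 measured members, of which 1 rose and 1 fell, also over the list alone (adjusted p = 0.740). ACTA2, smooth muscle actin, rose 1.57-fold, and PDGFRB, a PDGF receptor, was undetected with sorafenib and at least 1.22-fold lower. By fry, which tests whether a list's genes move 1 way on balance without comparing them with other genes, 11 lists were called: the 7 above, the PDI family (down, adjusted p = 0.0279), the ATF4 and CHOP targets (up; 0.0356), the synthetases (down; 0.0458) and the cytokine and interferon list.

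**Figure D3:**
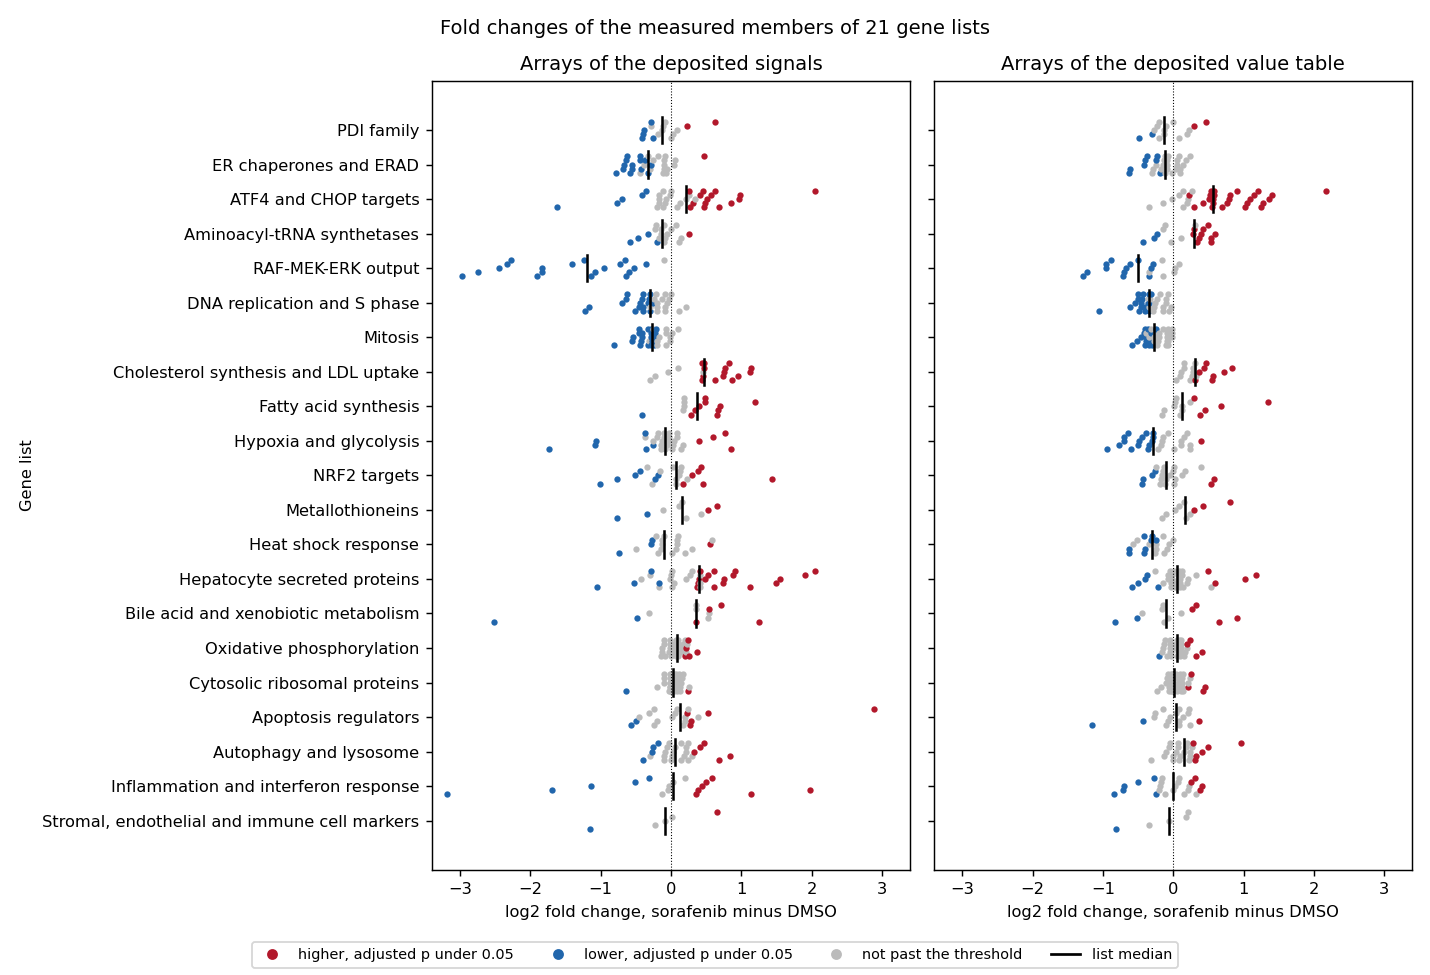
Log2 fold change, sorafenib minus DMSO (horizontal axis), of each measured member (points) of the 21 gene lists on the signal arrays (left) and the value-table arrays (right), with the list median as a black bar and colours for members past the adjusted threshold. The RAF-MEK-ERK median was -1.19 on the signal arrays and -0.51 on the value-table arrays.

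The value-table arrays carry the same sample labels, and their comparison, added after the data were seen, asked the same question. INHBE and STC2 had the largest rises. STC2, which encodes the secreted glycoprotein stanniocalcin 2, rose from a log2 level of 9.66 ± 0.19 to 11.83 ± 0.10 (SD, n = 3; log2 change 2.17, SE 0.10, limma adjusted p = 5.02e-05). INHBE, an inhibin beta chain of hepatocytes, rose 4.57-fold (log2 change 2.19, SE 0.13, adjusted p = 0.000231) and the asparagine synthetase ASNS 2.65-fold (SE of the log2 change 0.17, adjusted p = 0.00159). FST fell 2.58-fold, SPRY4 2.42-fold, from 11.01 ± 0.04 to 9.73 ± 0.18 (adjusted p = 0.000305), and DUSP6 2.34-fold, from 10.47 ± 0.11 to 9.24 ± 0.11 (adjusted p = 0.000303).

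Further rises on the value-table arrays included the anti-Mullerian hormone receptor AMHR2 (3.88-fold), the kinase ALPK2 (2.80-fold), NUPR1 (2.58-fold), ACSS2 (2.55-fold), the glycine transporter SLC6A9 (2.41-fold), the cysteine-forming enzyme CTH (2.37-fold), the mitochondrial carboxykinase PCK2 (2.30-fold) and KNG1 (2.27-fold). The cell cycle inhibitor CDKN1A fell 2.22-fold, the proteasome subunit PSMC4 2.29-fold, HOXD1 2.21-fold, the lysozyme gene LYZ 1.99-fold, the glycolytic mutase PGAM1 1.93-fold and the serum amyloid gene SAA4 1.88-fold. In all, 3038 of 17122 probes passed, 1555 higher and 1483 lower, against 5499 at an unadjusted p under 0.05; counted once per gene, 1199 of 10595 rose and 866 fell. Beyond 1.5-fold, 5 probes passed, 4 up and 1 down; of named genes these were STC2, INHBE, AMHR2, NUPR1 and FST. With the replicate block the counts were 5456 and 69, and without 1 array the first fell to 1676 (DMSO replicate 1), 1929 (DMSO replicate 3), 1560 (sorafenib replicate 1) and 1657 (sorafenib replicate 2).

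On these arrays 11 lists shifted by camera, and each call was lost with an estimated correlation. Of 35 ATF4 and CHOP targets, 26 rose and none fell, 27 and 1 when adjusted over the list alone and 29 and 1 with the replicate block (median log2 change 0.57, camera adjusted p = 5.06e-17, adjusted p = 0.118 with an estimated correlation). TRIB3 rose 2.07-fold and DDIT3 1.88-fold, and ATF4 had a log2 rise of 0.58. Of 18 aminoacyl-tRNA synthetases, 10 rose and 3 fell, 11 and 4 over the list alone (median 0.30, camera adjusted p = 0.0128, adjusted p = 0.390 with an estimated correlation). WARS1 rose 1.51-fold and AARS1 1.45-fold, while FARSA fell 1.35-fold. Of 19 RAF-MEK-ERK genes, 13 fell and none rose, 14 over the list alone (median -0.51, camera adjusted p = 6.38e-10, adjusted p = 0.118 with an estimated correlation), and CCND1 was 1 of those that fell (1.25-fold).

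The replication and mitosis lists fell by camera on the value-table arrays too. Of 32 replication and S phase genes, 17 fell and none rose, 23 over the list alone (median -0.34, camera adjusted p = 5.30e-11, adjusted p = 0.309 with an estimated correlation), with RRM2 2.08-fold lower. Of 35 mitosis genes, 14 fell and none rose, 20 over the list alone and 24 with the replicate block (median -0.27, camera adjusted p = 2.40e-08, adjusted p = 0.390 with an estimated correlation), and MKI67 fell by 0.58 on the log2 scale. Of 19 cholesterol genes, 8 rose and none fell, 10 over the list alone and 14 with the replicate block (median 0.30, camera adjusted p = 2.17e-05, adjusted p = 0.390 with an estimated correlation), with LSS 1.65-fold higher. Of 14 fatty acid genes, 5 rose and none fell, also over the list alone (median 0.12, camera adjusted p = 0.0159, adjusted p = 0.390 with an estimated correlation).

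The hypoxia and glycolysis list and the heat shock list fell by camera on the value-table arrays. In the hypoxia and glycolysis list, 15 of 28 genes fell and 1 rose, 18 and 1 over the list alone and 17 and 3 with the replicate block (median -0.28, camera adjusted p = 1.06e-06, adjusted p = 0.113 with an estimated correlation). PGAM1 and ADM, which encodes the vasodilator adrenomedullin, fell 1.93-fold and 1.70-fold, whereas the angiogenic factor VEGFA rose 1.32-fold. Of 19 heat shock genes, 8 fell and none rose, 12 over the list alone and 13 with the replicate block (median -0.30, camera adjusted p = 6.10e-08, adjusted p = 0.118 with an estimated correlation), among them the co-chaperones BAG3 (1.55-fold) and CHORDC1 (1.55-fold). Of 30 ER chaperone and degradation genes, 8 fell and none rose, 11 and 1 over the list alone and 11 and 2 with the replicate block (median -0.12, camera adjusted p = 0.00276, adjusted p = 0.231 with an estimated correlation). SDF2L1 and CRELD2, both ER stress-induced, fell 1.54-fold and 1.53-fold, and HSPA5 1.29-fold, while XBP1 had a log2 change of -0.07 (adjusted p = 0.558). Of 25 autophagy and lysosome genes, 6 rose and none fell, also over the list alone, and 10 and 1 with the replicate block (median 0.15, camera adjusted p = 0.00791, adjusted p = 0.130 with an estimated correlation), with NEU1 1.95-fold higher and ULK1 higher by 0.49 on the log2 scale.

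The remaining lists were not called by camera on the value-table arrays. Of 15 PDI family genes, 2 rose and 2 fell, 4 and 4 over the list alone and 4 and 5 with the replicate block (adjusted p = 0.384); P4HB had a log2 change of 0.09 (adjusted p = 0.319). Of 34 secreted hepatocyte genes, 4 rose and 5 fell, also over the list alone, and 8 and 5 with the replicate block (adjusted p = 0.584), with the coagulation factor gene F7 2.04-fold higher and the ferroxidase gene CP lower by a log2 change of -0.59. ALB and AFP had log2 changes of 0.04 and -0.03 (adjusted p = 0.924 and 0.871), and MCL1 had a log2 change of -0.15 (adjusted p = 0.188). Of 10 metallothionein list genes, 3 rose and none fell, 4 over the list alone and 6 with the replicate block (adjusted p = 0.0511, 0.0240 with the block and, without it, adjusted p = 0.390 with an estimated correlation), led by MT1B (1.75-fold). Of 22 NRF2 targets, 2 rose and 4 fell, 3 and 4 over the list alone and 3 and 8 with the replicate block (adjusted p = 0.161). Of 12 bile acid and xenobiotic genes, 4 rose and 2 fell, 4 and 3 over the list alone (adjusted p = 0.886; median -0.10, down by camera and up by fry), with SULT2A1 1.87-fold higher and UGT1A1, the bilirubin transferase, under the filter's level with sorafenib and at least 1.45-fold lower.

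Of 23 cytokine and interferon genes on the value-table arrays, 4 rose and 6 fell, 5 and 7 over the list alone and 8 and 8 with the replicate block (camera adjusted p = 0.376; median 0.00254, mean -0.08, down by camera). CXCL8 fell 1.80-fold and CCL20 1.64-fold, and IFIT3 rose 1.32-fold. Of 17 apoptosis regulators, 1 rose and 2 fell, 1 and 3 over the list alone and 3 and 4 with the replicate block (adjusted p = 0.651; median 0.04, mean -0.06, down by camera), with CDKN1A the largest fall. Of 32 oxidative phosphorylation genes, 4 rose and 1 fell, also over the list alone, and 5 and 2 with the replicate block (adjusted p = 0.376). Of 37 ribosomal protein genes 4 rose and none fell, 2 over the list alone and 6 and 2 with the block (adjusted p = 0.384). Of 5 measured stromal, endothelial and immune markers, CD3D fell 1.76-fold and none rose, also over the list alone, and 2 fell with the replicate block (adjusted p = 0.376). By fry 11 lists were called on these arrays, with the metallothioneins (adjusted p = 0.0440) and the stromal, endothelial and immune markers (0.00580) in place of mitosis (0.0886) and fatty acid synthesis (0.0554).

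Genes called on both sets mostly moved the same way. Of 9560 genes tested in both, 532 rose in both, where independent lists would share 167, and 403 fell in both, where independent lists would share 114. Another 24 rose on the signal arrays and fell on the value-table arrays, and 25 did the opposite, so that 935 of 984 genes called in both moved the same way. Across probes kept in both, with the signals taken without background correction, fold changes correlated at a Pearson r of 0.502 and a Spearman rho of 0.481. Leading genes of the signal arrays without a probe past the value-table filter, and so not tested there, were DKK4, NR0B2, IGFBP1, MIXL1, PPP2R2C, TAGLN3, GNMT, PLA2G1B, TNNC2, DIO1, GSTA5, PNCK, CLIC3 and WFIKKN1. Others did not pass there. BMF and CAPN3, at DMSO means of 7.63 and 7.49 just above the filter's level of 7.40, had log2 changes of 0.22 (adjusted p = 0.140) and 0.11 (0.448), and a missing call so near that level says little. APOC3 had a log2 change of 0.53 (0.132), HEY1 of -0.33 (0.0843) and GDF15 of -0.35 (0.115). With the replicate block APOC3 (adjusted p = 1.81e-05), HEY1 (0.00404) and GDF15 (0.000664) passed there. In the other direction, STC2 had a log2 change of -0.01 (adjusted p = 0.949) and ASNS of -0.12 (adjusted p = 0.510) on the signal arrays, whereas INHBE rose there by 1.70 on the log2 scale (SE 0.08, adjusted p = 2.66e-06). Whether any of these changes differed between the sets was not tested.

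**Figure D4:**
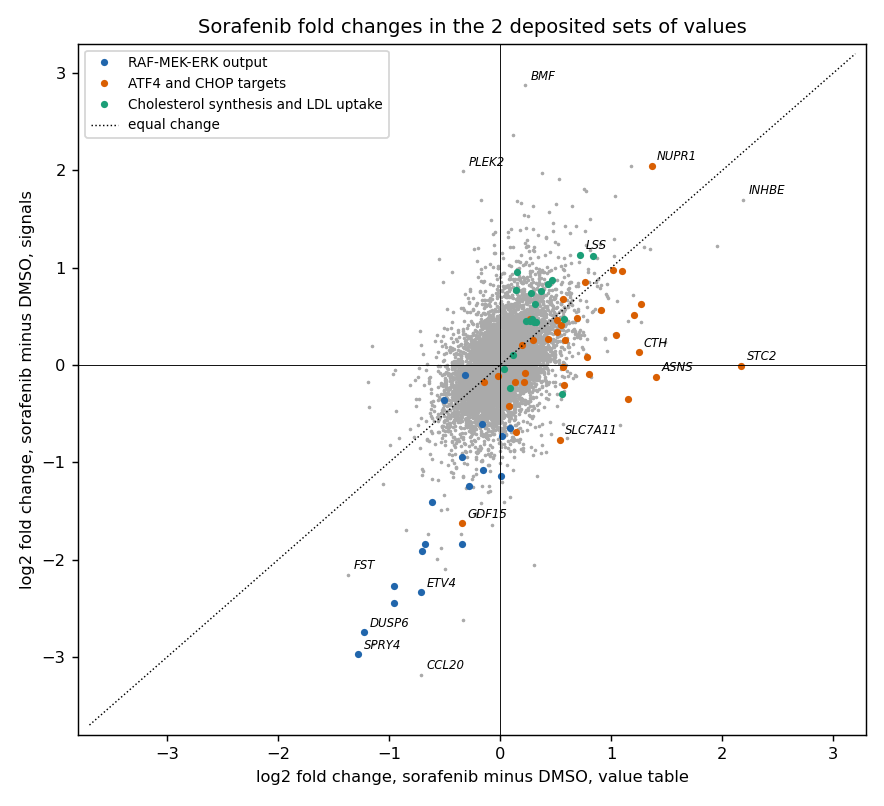
Log2 fold change of each gene, sorafenib minus DMSO, on the value-table arrays (horizontal axis) against the signal arrays (vertical axis), with 3 gene lists in colour and a dotted line of equal change. Of 984 genes called in both sets, 935 moved the same way.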

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

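The value table was added as a separate set after the data were seen, and the test of it as another normalization was chosen after its result had been seen. The results named here stand out because every sorafenib sample of one set lay above every DMSO sample, or the list mean lay above 0, and the opposite held in the other set. These differences were not tested, and the sets were normalized separately.

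PLEK2, a pleckstrin family gene, had a log2 change of 1.99 on the signal arrays (limma adjusted p = 2.25e-05) and -0.33 on the value-table arrays (0.0586, and 0.00693 with the replicate block), a difference of 2.33. Its DMSO mean on the signal arrays, 6.39, lay near their detection level. SLC7A11, the cystine transporter, had changes of -0.77 (0.0245) and 0.54 (0.00416), a difference of -1.30; its call on the signal arrays was lost without DMSO replicate 1 (-0.74) or DMSO replicate 2 (-0.72). HMOX1, heme oxygenase, had changes of 0.46 and -0.12, a difference of 0.58, of which the value-table change did not pass (adjusted p = 0.344). MT2A, a metallothionein, had changes of -0.76 and 0.18, a difference of -0.95, of which the value-table change did not pass (adjusted p = 0.0794, but 0.0104 with the replicate block). AKR1C3, an aldo-keto reductase, had changes of 0.38 and -0.45, a difference of 0.83, and HP, haptoglobin, 0.38 and -0.51, a difference of 0.89. Both passed in both sets. On the value-table arrays AKR1C3 lay at 8.14 with DMSO and 7.69 with sorafenib, near the filter's level of 7.40. Its means on the signal arrays were 14.88 and 15.26. SLC7A11 lay at 7.61 with DMSO and 8.14 with sorafenib on the value-table arrays, near the filter's level too. An opposite sign so near that level is weak evidence of an opposite response. The mean of the aminoacyl-tRNA synthetases was -0.13 on the signal arrays (camera adjusted p = 0.0816) and 0.19 on the value-table arrays (0.0128), a difference of -0.32.

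The pattern behind these genes is that the 2 sets differ probe by probe although they carry the same labels. Another normalization of the same arrays was tested and argued against, since the highest Spearman correlation of a sample's own 2 columns, 0.863, lay below the lowest between different arrays of 1 set, 0.923. Shuffled probe identifiers were argued against as well, since the levels of 2 probes of a gene correlated across 2933 genes at 0.418 in the signals and 0.403 in the value table. The differences between the sets correlated at 0.812 between 2 probes of a gene, which is consistent with different cell populations behind the sets. No biological explanation that the groups of the design give was tested, and which set matches its labels stays open.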

How the results depend on the processing

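The value table's own comparison and its alternatives were added after the data were seen. All other alternatives were planned. The value table holds other arrays, so results with it in place of the signals do not show sensitivity to processing alone. Direction was judged only for genes that passed. Of 93 named genes, all kept the call on the signal arrays without background correction and with normexp, cyclic loess, array weights or the replicate block. The 81 detected on all arrays kept it as well. None of these genes that passed changed direction in these settings. Calls lost, none with a change of sign, numbered 11 with median scaling, 7 without the intensity trend, 3 with the mean of probes, 1 with no filter, 1 with the robust prior and at most 9 without 1 array (DMSO replicate 2). Of named genes and of lists by camera, the replicate block ended no call on either set and gained no call of a gene or list named on that set other than those given with it; fry was not run with it. The cause of the differences named here was not tested. Dim probes set the limit of the bounds given for undetected genes.

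The count of changed probes (4582) was 2627 with median scaling and 2582 with the value table, and 2946 (without DMSO replicate 2) to 4338 without 1 array. The count beyond 1.5-fold (221) was 135 without background correction, 147 with normexp, 6 with the value table and 409 with the replicate block, and 142 (without sorafenib replicate 2) to 260 without 1 array, with 144 without DMSO replicate 2. The number of lists (7) was 11 with the value table, 0 with the estimated correlation and 7 to 8 without 1 array. On the value-table arrays the probe count (3038) was 5456 with the replicate block and 1560 to 2494 without 1 array, with 1676 without DMSO replicate 1, 1929 without DMSO replicate 3 and 1657 without sorafenib replicate 2; lists (11) numbered 10 to 11.

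With an estimated correlation the adjusted p was 0.207 for ER chaperones, 0.550 for RAF-MEK-ERK output, 0.674 for S phase, mitosis, cholesterol and fatty acid synthesis, and 0.689 for hepatocyte proteins, ATF4 targets and synthetases. In 17 other settings of the signals the 7 called lists stayed at or below 0.00344. The ATF4 list (0.0687) was called at 0.0286 with array weights, 0.0363 with the mean of probes and 1.00e-18 with the value table, and ran from 0.00768 (without sorafenib replicate 3) to 0.175 without 1 array. The synthetases (0.0816, down) ran from 0.0455 (without sorafenib replicate 2; 0.0489 without sorafenib replicate 1) to 0.239, and with the value table turned up at 0.00728. With the value table, hypoxia (2.35e-06), heat shock (3.37e-08) and autophagy (0.0106) were called and hepatocyte proteins were not (0.308). Over 17 settings of the signals at the preset correlation the ATF4 list ran from 0.00768 to 0.175. Over all 19 settings it ran from 1.00e-18, with the other arrays of the value table, to 0.689, with the estimated correlation.

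With values taken from the value table, 49 of the 93 genes kept the call, and the direction where they passed. Another 32 lost the call (DKK4 and others under that set's own filter among them), and 1 gained it. The remaining 11, which passed on the signal arrays, had the other sign. Genes that passed in neither were not judged by direction, such as P4HB with log2 changes of -0.12 and 0.09. Of the 11 genes with the other sign, only SLC7A11 (0.54) passed (adjusted p = 0.00435). In the value table SLC7A11 lay at 7.61 with DMSO and 8.14 with sorafenib, near the filter's level of 7.40. PLEK2 (-0.33), HMOX1 (-0.12), MT2A (0.18), HSPB1 (-0.0934) and ATG16L1 (0.00135) did not pass. PNCK (-0.23), TAGLN3 (0.0478), MIXL1 (0.0206), ACTA2 (-0.0426) and PDGFRB (0.0515) did not pass either and lay under that set's own filter. The filter's level was taken from the signals, so whether these values are background was not measured. Their signs there say little.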

Other observations

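The test of the RAF-MEK-ERK list's background was chosen after its result had been seen, and the splits of the value-table arrays belong to a comparison added after the data were seen. The beta-catenin targets were listed before their levels were read, but after other genes of that kind had been seen to differ. Single genes with large differences in level between the sets follow. Signals without background correction put the imprinted gene DLK1 at 14.49 and the value table at 6.56, and the zinc finger gene PEG3 lay at 14.17 and 6.88. Smooth muscle actin ACTA2 lay at 13.27 and 6.89, and the thyroxine-binding globulin gene SERPINA7 at 12.88 and 6.79. In the other direction, fibrinogen FGB lay at 7.60 in the signals and 14.48 in the value table, the trypsin inhibitor SPINK1 at 7.28 and 14.62, the glutathione transferase GSTP1 at 8.52 and 15.19, and vimentin VIM at 6.69 and 13.21. These genes were chosen after their values were seen, and their levels come from separately normalized sets.

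The sets were also compared in the levels of listed targets of beta-catenin, the transcriptional effector of WNT signalling, across separately normalized values. All 6 measured of 7 listed targets were higher in the signals: AXIN2 by 4.63 log2 units, SP5 by 3.90, ZNRF3 by 2.18, RNF43 by 2.00, NOTUM by 5.10 and TNFRSF19 by 3.90. Their median difference of 3.90 lay at percentile 100 of 10000 random lists of the same size and mean level, of which the central 95 percent ran from -0.50 to 0.81. A candidate explanation is that the signals came from another of the lines named in the series design, such as HepG2, which is known to carry an activated beta-catenin and to lack CD81. No reference profile of these lines was used here. Both traits go with the candidate, and genes that would go against it were not searched for. FGB lay at 7.60 in the signals, near their detection level of 7.36 to 7.44 without background correction, and at 14.48 in the value table. Such a low level would go against any line that makes fibrinogen, and whether the named lines do was not checked. The candidate stays a hypothesis.

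The median log2 change of the same 18 RAF-MEK-ERK genes was -0.43 on the value-table arrays and -1.33 on the signal arrays, a difference that was not tested. The median of the signals without background correction was -1.22, so leaving out the subtraction did not give the smaller median on the signal arrays. A missing subtraction shrinks the changes of dim genes more than those of bright genes. With DMSO, SPRY4 and DUSP6 lay at 13.11 and 11.53 in the background-corrected signals and at 11.01 and 10.47 in the value table. The check therefore cannot exclude a larger effect on the value-table arrays. A difference between the cells behind the sets is another possible explanation.

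The 6 arrays of a set make 10 splits into 3 and 3, too few for a share under 0.05. Every split other than the real one mixed DMSO and sorafenib arrays. Such a split keeps part of the sorafenib difference and puts the rest into the spread within its groups, which hinders calls of single probes. The other splits therefore do not show what would be called without a sorafenib effect. The real split called 4582 probes on the signal arrays and 3038 on the value-table arrays, and the highest other split 0 and 0; for changes beyond 1.5-fold the numbers were 221 and 0. By camera, 7 lists were called on the signal arrays, against 9 in the highest other split and 8 in the highest split that also parts all same-numbered pairs; 6 of the 10 splits, the real one included, gave at least as many. On the value-table arrays camera called 11 lists against 9 in the highest other split. By fry, 11 lists were called on each set, against 0 and 1. For each of these counts other than that of camera on the signal arrays, 1 of the 10 splits, the real one, gave a result as large.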
